A study of Mus musculus with 6 samples.

How the data were processed

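Liver RNA of 6 mouse samples was analysed, 3 of a control group labelled wild type and 3 of a group in which both Sox9 alleles were floxed and Cre recombinase was driven by the albumin promoter (Sox9 cKO). Per the labels' protocols, total RNA was extracted with Trizol, RNA integrity numbers were above 9, stranded mRNA libraries were made with a TruSeq kit, and single-end reads of 75 nt were read on an Illumina NextSeq sequencer. Per the series' design text and the submitters' processing notes, the authors trimmed reads with Trim Galore 0.5.0 and cutadapt 1.16, aligned them to mouse genome build mm10 with STAR 2.6.0a, and estimated expression with RSEM 1.3.1. The gene annotation and the strand setting of RSEM are not given in the sources used here. Ages and sexes of the animals are not given in the labels.

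The authors deposited 1 table of TPM, the share of transcripts scaled to a fixed total, with 24411 rows and 1 column per library, each summing to 1000000. TPM divides each gene's estimated reads by its length and scales the library to a fixed total. Sequencing depth is therefore unknown, a large change in a few abundant genes lowers or raises all others, and no counting interval was computed. Columns were matched to samples through the library numbers in the labels. In 27 rows a calendar date stood in place of the gene symbol, and 4 of these rows had a duplicated name. They were kept in the tests and are not named. None of the 13 mitochondrially encoded genes of a list fixed beforehand had a row in the table. RSEM divides reads among near-identical genes, so values of single Mup, Sult2a, Cyp2b, Cyp3a, Cyp4a12 and hemoglobin genes are uncertain. With the strand setting not given, overlapping antisense genes are uncertain too.

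Genes with a mean of at least 0.5 TPM over the 6 libraries were tested, which left 12539. Values were transformed to log2(TPM + 0.5) and fitted in limma 3.58.1 (R 4.3.3) with group as the only term, using empirical Bayes moderation with a variance trend. Tests were two-sided, p-values were adjusted by the Benjamini-Hochberg method over all tested genes, and the threshold was an adjusted p of 0.05. Fold changes are Sox9 cKO minus control on the log2(TPM + 0.5) scale, which understates the change of genes with low values. Errors are standard errors (SE) of the fit or standard deviations (SD) of TPM over 3 libraries. Sox9 was also compared by an exact permutation test.

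The test, the samples, 36 gene lists and the rule for named genes were fixed before the data were examined. The rule took Sox9, the 12 genes with the largest fitted change in each direction among genes past the threshold with non-overlapping groups (predicted genes and pseudogenes left out), up to 4 members of each list past the threshold over all genes or over the list alone, 24 genes fixed by name, 5 sex-linked genes and Nnt. Members named outside it to complete a count were chosen after their values were seen. Some genes that the rule takes are not reported here. Each list with at least 3 tested genes was compared with all other genes by camera in limma with a preset inter-gene correlation of 0.01, adjusted over 35 lists. Camera with an estimated correlation and fry, which asks whether the genes of a list move on balance in one direction, were run beside it. Gene positions were taken by symbol from the GENCODE annotation of GRCm38, the assembly of mm10, for 23306 genes and from RefSeq for 983, and 122 had none.

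Alternatives fixed at the same time were other pseudocounts, other filters on low values, median centring, rescaling without the 50 most abundant genes, quantile normalization, a fit without the variance trend, array weights, a replicate block, and leaving out each library in turn. A sex-marker term (Xist above 10 TPM) and a fit without control replicates 1 and 2 were added after the data were seen. The model was tested on data simulated from the means and residual SDs of the 12539 genes in this comparison. It recovered 52% of 100 genes changed 2-fold and 92% of 100 genes changed 4-fold, called 13 unchanged genes, and called 0 genes in a simulation without changes. The changed genes were drawn only from genes with a mean of at least 5 TPM. Recovery of genes below that level, such as Sox9, was not measured. Noise was drawn independently for each gene and library, without a shift common to all genes or correlation between genes. The rate of false calls in the real data was therefore not measured. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.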

Results

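Gene expression was measured by mRNA sequencing in 3 control liver samples and 3 liver samples of mice carrying floxed Sox9 alleles and an albumin-driven Cre (Sox9 cKO), which deletes Sox9 in liver epithelial cells. The comparison asked how loss of SOX9, a transcription factor of bile duct cells, alters the liver transcriptome during postnatal bile duct maturation. Between 15266 and 15506 genes had a value above 0 in the control libraries and between 14649 and 14991 in the Sox9 cKO libraries. Depth is unknown because TPM does not retain it. The labels do not state that every library came from a separate animal, so the p-values measure the spread between these samples.

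Sox9 (chromosome 11, 112782224 to 112787760, mm10) was lower in all 3 Sox9 cKO libraries than in all 3 control libraries. Its level was 1.52 ± 0.150 TPM in controls and 0.423 ± 0.246 TPM in Sox9 cKO (SD, n = 3 each), so that 27.9% of the control mean remained. The single values were 1.69, 1.43 and 1.43 TPM in controls and 0.19, 0.40 and 0.68 TPM in Sox9 cKO. The log2 fold change was -1.16 (SE 0.25, limma adjusted p = 0.0323). The exact two-sided permutation test gave p = 0.1, the smallest value 3 against 3 samples allow. The table holds 1 value per gene, so reads from deleted and retained exons were not separated. Cre transcripts were not analysed here, so the level of Sox9 is the only check of the genotype labels. Median centring (adjusted p = 0.0903), quantile normalization (0.226) and leaving out any 1 library other than Sox9 cKO replicate 3 (0.0620 to 0.115) ended the call.

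Of 12539 tested genes, 103 were higher and 1099 were lower in Sox9 cKO. Lower genes made up 91.4% of these calls. The median log2 fold change over all tested genes was -0.24, and changes below are to be read relative to that shift. After median centring 144 genes were higher and 284 lower, or 66.4% lower, and after quantile normalization 120 were higher and 215 lower, or 64.2% lower. The groups did not overlap for 4700 genes, or 37.5%, against 10% given by chance. The first principal component held 58.4% of the variance and separated the groups. Pearson correlations across genes, which are not independent replicates, were 0.977 to 0.987 among controls, 0.966 to 0.975 among Sox9 cKO libraries and 0.939 to 0.965 between groups. Leaving out control replicate 2 left 32 higher and 104 lower genes, control replicate 1 left 45 and 158, and control replicate 3 left 50 and 267. Without Sox9 cKO replicate 1 there were 76 higher and 591 lower genes, and without Sox9 cKO replicate 2 there were 92 and 718.

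The sex markers differed between the groups. Xist, which is expressed from the inactive X chromosome of females, was at 114 and 123 TPM in control replicates 1 and 2, at 0.01 TPM in control replicate 3, and at no more than 0.02 TPM in the Sox9 cKO libraries. Eif2s3y, a gene of the Y chromosome, was at 51.6 TPM in control replicate 3 and at 47.6 to 49.9 TPM in Sox9 cKO, but at 0.07 and 0 TPM in control replicates 1 and 2. Ddx3y, Kdm5d and Uty were likewise above 0 only in control replicate 3 and the 3 Sox9 cKO libraries. None of the 5 sex-linked genes passed the limma test over all genes, while 4 were higher and 1 was lower when adjusted over the list alone. Adding a sex-marker term after this was seen left 21 higher and 49 lower genes, and leaving out control replicates 1 and 2 left 9 higher and 18 lower. Both of these fits rest on control replicate 3 as the only control with Y-linked transcripts. Every gene and list difference described in what follows was measured across this imbalance.

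The largest increases were in genes with higher expression in male than in female mouse liver. Of 18 tested members of the male-biased list, 16 rose and 0 fell (17 rose adjusted over the list alone), with a median log2 fold change of 4.55. Cyp4a12a, a fatty acid hydroxylase, was at 0.187 ± 0.170 TPM in controls and 180 ± 81.1 TPM in Sox9 cKO (log2 fold change 7.94, SE 0.37, adjusted p = 2.84e-04). Hsd3b5, a steroid dehydrogenase, was at 0.433 ± 0.379 and 155 ± 130 TPM (7.09, SE 0.61), and Slco1a1, an organic anion transporter, at 1.26 ± 0.358 and 169 ± 88.3 TPM (6.49, SE 0.34). Elovl3, a fatty acid elongase, rose by a log2 fold change of 4.99 (SE 0.79). Major urinary protein genes Mup7, Mup19, Mup15, Mup1, Mup2 and Mup12 rose by log2 fold changes of 6.28 to 9.65, and Mup14 was listed at 0 in every control and at 59.5, 522 and 2078 TPM in Sox9 cKO. Mup genes together held 0.0206% to 0.150% of TPM in controls and 1.42% to 3.40% in Sox9 cKO. Leaving out control replicate 1 left 10 risen members. The camera test placed the list above other genes (adjusted p = 7.95e-40), but not with an estimated correlation (adjusted p = 0.215).

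Genes with higher expression in female liver were lower, and Sult2a1 had the largest fitted decrease of the named genes. Of 20 tested members of the female-biased list, 11 fell and 0 rose (15 fell adjusted over the list alone), with a median log2 fold change of -4.03 (camera adjusted p = 2.55e-05, and adjusted p = 0.310 with an estimated correlation). Sult2a1, a sulfotransferase of steroids and bile acids, was at 849 ± 28.2 TPM in controls and at 6.11, 0.39 and 0 TPM in the Sox9 cKO libraries (log2 fold change -9.21, SE 0.81, adjusted p = 0.00289). Sult2a2 and Sult2a5 fell by log2 fold changes of -7.18 and -7.11, and Sult2a3 was listed at 0 in every Sox9 cKO library and at 8.25 to 21.2 TPM in controls. Cyp3a16 fell (-6.50, SE 1.14), with 162 and 211 TPM in control replicates 1 and 2 and 6.53 TPM in control replicate 3. A1bg (-5.59) and Hao2 (-4.78) also fell. Cyp2b13 had a log2 fold change of -5.89 (adjusted p = 0.0474) with 67.1, 0.50 and 0.47 TPM in the Sox9 cKO libraries, and its call was lost in 15 of 19 other settings, with fold changes from -7.93 to -3.68. Sult2a2 lost its call in 9 of 19. Without control replicate 1 or control replicate 2 only 3 members of the list passed, and without Sox9 cKO replicate 3, or after median centring, there were 7. Control replicate 3, although it expressed Y-linked genes, had 842 TPM of Sult2a1 and 0.06 TPM of Cyp4a12a. Against this library alone the median log2 difference of the 3 Sox9 cKO libraries was 5.48 for the male-biased list and -2.75 for the female-biased list. With the sex-marker term 9 members of the male-biased list and 3 of the female-biased list passed.

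**Figure D1:**
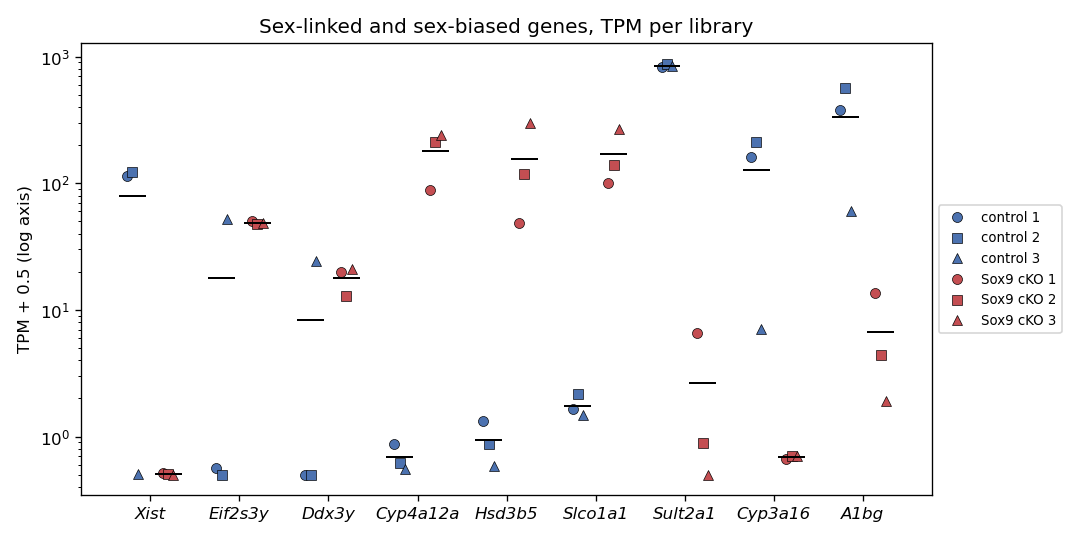
Points give TPM + 0.5 on a log axis for each of the 6 libraries (blue controls, red Sox9 cKO, shape for replicate), and bars give group means. Control replicate 3 had 51.6 TPM of Eif2s3y, near the Sox9 cKO libraries, but 0.06 TPM of Cyp4a12a and 842 TPM of Sult2a1, near the other controls.

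Of 26 tested structural and identity markers of bile duct cells (cholangiocytes), 7 fell and 1 rose, and 19 fell and 1 rose adjusted over the list alone (camera adjusted p = 0.00147, and adjusted p = 0.297 with an estimated correlation). Prom1, a membrane glycoprotein of progenitor cells that is also in the female-biased list, went from 17.9 ± 4.85 to 1.70 ± 1.57 TPM (log2 fold change -3.25, SE 0.45, adjusted p = 0.00948). Tspan8, a tetraspanin, went from 3.76 ± 0.733 to 0.663 ± 0.217 TPM (-1.87), and Elf3, an epithelial transcription factor, from 1.94 ± 0.207 to 0.170 ± 0.0954 TPM (-1.87). Bicc1, an RNA-binding protein linked to cystic disease, fell by 1.34 on the log2 scale, and Mal2, a protein of apical transport, rose by 0.52. With a replicate block 0 members rose, which ended the Mal2 call. Krt19 was at 1.39 ± 0.201 TPM in controls and 1.23 ± 0.411 TPM in Sox9 cKO (adjusted p = 0.694). Krt7 (adjusted p = 0.117), Epcam (0.530) and Spp1 (0.251) did not pass either, with log2 fold changes between -0.64 and -0.27. With the sex-marker term 0 members passed, and without any 1 of the control replicates 3 fell, as many as after median centring.

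**Figure D2:**
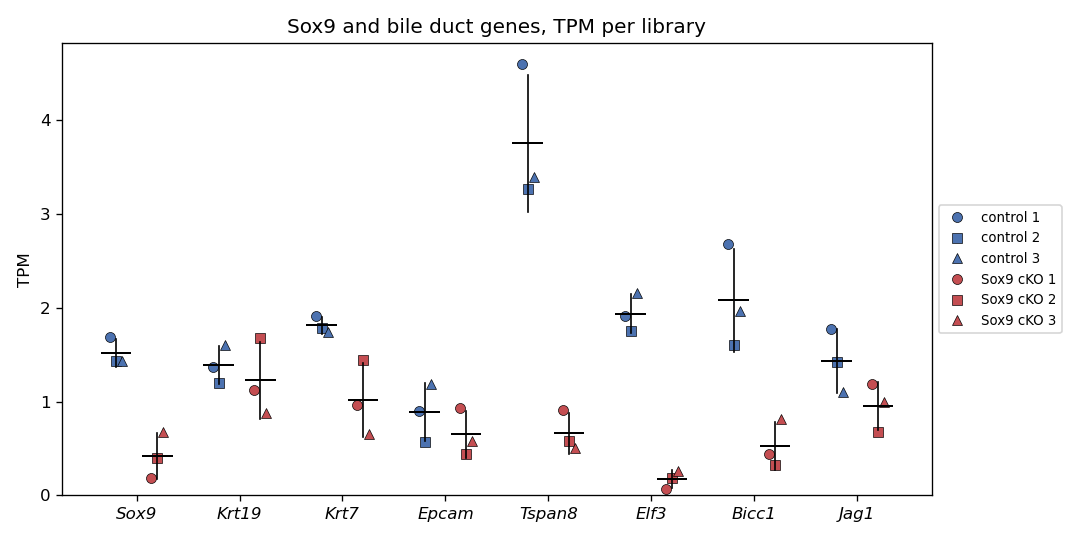
Points give TPM for each of the 6 libraries (blue controls, red Sox9 cKO, shape for replicate), horizontal bars group means and vertical bars the SD (n = 3). The groups do not overlap for Sox9, Krt7, Tspan8, Elf3 and Bicc1, although Krt7 did not pass the limma test (adjusted p = 0.117). Krt19 averaged 1.39 TPM in controls and 1.23 TPM in Sox9 cKO.

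Cholangiocyte transport, receptor and cilium genes had 1 of 12 tested members past the threshold, Pkd2, a cation channel of primary cilia, which fell by 0.76 on the log2 scale (1 adjusted over the list alone, camera adjusted p = 0.345). The chloride channel gene Cftr and the secretin receptor gene Sctr were at no more than 0.12 TPM in any library and were not tested. Among Notch pathway genes, which act in bile duct formation, 2 of 12 fell, namely Notch2 (log2 fold change -0.91, SE 0.19) and Lfng (-0.98, SE 0.21), and 7 fell adjusted over the list alone (camera adjusted p = 0.0169, and adjusted p = 0.310 with an estimated correlation). The Notch call was lost under quantile normalization (adjusted p = 0.202), and without any 1 of the controls 0 Notch and 0 cholangiocyte transport genes passed. Jag1 had a log2 fold change of -0.41 (adjusted p = 0.275) and Hes1 of -0.04 (adjusted p = 0.896). The Hippo-YAP list holds pathway components such as Tead1 beside target genes. Of its 12 tested members 2 fell, Axl (-1.39) and Tead1 (-0.80), and 3 fell adjusted over the list alone (camera adjusted p = 0.415). Called members numbered 0, 0 and 1 without control replicates 1, 2 and 3, and the Tead1 call was lost in 12 of 18 other settings. Of 11 TGF-beta pathway genes 3 fell over all genes and over the list alone, among them Tgfb1 (-1.01) and Thbs1 (-1.22), with a camera adjusted p of 0.0689, and adjusted p = 0.456 with an estimated correlation. The TGF-beta list passed without a filter (0.0194), after median centring (0.0404), after rescaling (0.0388), without the variance trend (0.0427), without control replicate 2 (0.0349) and without Sox9 cKO replicate 3 (0.0298). Called TGF-beta genes numbered 0 without control replicate 1 or 3 and 1 without control replicate 2. After median centring 0 Notch, 0 cholangiocyte transport, 1 Hippo-YAP and 1 TGF-beta gene passed.

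Extracellular matrix genes were lower together. Of 25 tested members 20 fell and 0 rose (24 fell adjusted over the list alone), with a median log2 fold change of -1.28 (camera adjusted p = 1.04e-13, and adjusted p = 0.215 with an estimated correlation). Col3a1 went from 51.3 ± 4.62 to 15.1 ± 4.61 TPM (-1.78, SE 0.23, adjusted p = 0.00746), Col1a1 from 7.38 ± 1.94 to 2.28 ± 1.03 TPM (-1.53, SE 0.30, adjusted p = 0.0243), and Timp1, an inhibitor of matrix proteases, from 4.58 ± 0.503 to 0.460 ± 0.0265 TPM (-2.40, SE 0.18). Of 19 genes of hepatic stellate cells and portal fibroblasts 7 fell (10 over the list alone), among them Vim (-1.34), Cygb (-1.32) and Pdgfrb (-1.16), with camera adjusted p = 2.58e-04, and adjusted p = 0.297 with an estimated correlation. Acta2, a marker of activated stellate cells, had a log2 fold change of -0.58 (adjusted p = 0.336). Without control replicate 1, 2 or 3 there were 8, 7 or 10 called matrix genes and 2, 0 or 2 called stellate cell genes. After median centring 13 matrix genes and 3 stellate cell genes passed as lower, and with the sex-marker term 2 and 0.

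Genes of immune cells and inflammation were lower as well. Of 21 Kupffer cell and macrophage genes 14 fell (19 over the list alone), with a median of -1.42 (camera adjusted p = 9.89e-09, and adjusted p = 0.297 with an estimated correlation). Cd14, a receptor for bacterial lipopolysaccharide, went from 10.7 ± 0.577 to 1.02 ± 0.317 TPM (-2.90, SE 0.20), and Marco, a scavenger receptor, from 30.7 ± 8.07 to 6.23 ± 2.39 TPM (-2.25, SE 0.29). Adgre1, which encodes F4/80, had a log2 fold change of -1.64 and did not pass (adjusted p = 0.0523). Of 7 neutrophil genes 6 fell (7 over the list alone; camera adjusted p = 2.58e-04, and adjusted p = 0.236 with an estimated correlation), including S100a9 (-4.09) and S100a8 (-2.71). Of 13 chemokine and cytokine genes 8 fell (12 over the list alone), including Cxcl1 (-2.53), Ccl2 (-2.13) and Il1b (-2.04), with camera adjusted p = 1.62e-06, and adjusted p = 0.215 with an estimated correlation. Of 20 acute phase genes 9 fell (17 over the list alone; camera adjusted p = 4.39e-05, and adjusted p = 0.297 with an estimated correlation). Lcn2, an iron-siderophore binding protein of the acute phase, went from 279 ± 114 to 12.2 ± 3.07 TPM (-4.42, SE 0.30, adjusted p = 6.72e-04), and Saa2 fell by 2.71 on the log2 scale. Called macrophage genes numbered 3, 3 and 6 without control replicates 1, 2 and 3, 4 without Sox9 cKO replicate 1, 8 without Sox9 cKO replicate 2, and 5 after median centring. After median centring 3 neutrophil, 5 chemokine and 2 acute phase genes passed. Leaving out a control replicate left 0 to 3 neutrophil, 2 to 5 chemokine and 2 to 4 acute phase genes, lowest without control replicate 2, 2 and 1. Without Sox9 cKO replicate 1 there were 3 neutrophil, 5 chemokine and 3 acute phase genes, and without Sox9 cKO replicate 2 there were 3 neutrophil genes. With the sex-marker term 1 macrophage, 2 neutrophil, 2 chemokine and 4 acute phase genes passed.

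Of 12 lymphocyte genes 2 fell, Ptprc (-1.46) and Gzma (-1.32), and 8 adjusted over the list alone (camera adjusted p = 0.0108, and adjusted p = 0.456 with an estimated correlation), a call lost with the sex-marker term (0.0766), without control replicates 1 and 2 (0.0544), without Sox9 cKO replicate 2 (0.0553) and with array weights (0.0514). Of 22 interferon response genes 4 fell (6 over the list alone), among them Gbp2 (-1.95) and Ifit2 (-1.19), with camera adjusted p = 0.00745, adjusted p = 0.591 with an estimated correlation and 0.183 with the sex-marker term. Of 20 endothelial genes 4 fell (8 over the list alone), Cdh5 (-0.99), Fcgr2b (-0.85), Stab2 (-0.69) and Gpr182 (-0.58), with camera adjusted p = 0.0231, and adjusted p = 0.591 with an estimated correlation. The endothelial call was lost without Sox9 cKO replicate 2 (0.0907), without Sox9 cKO replicate 3 (0.0639) and with array weights (0.264). Of 11 erythroid and hematopoietic genes 3 hemoglobin genes fell, Hbb-bs (-5.11), Hba-a1 (-2.53) and Hbb-bt (-2.15), and Alas2, an enzyme of heme synthesis, rose (1.40), with 4 lower and 1 higher over the list alone (camera adjusted p = 0.533). Hbb-bs was at 16.5, 0 and 0 TPM in Sox9 cKO, and its call was lost in 14 of 19 other settings, with fold changes from -6.81 to -2.88. Without any 1 of the controls 0 erythroid genes and 0 endothelial genes passed, lymphocyte genes numbered 0, 0 and 1, and interferon genes 1, 1 and 2 without control replicates 1, 2 and 3. After median centring 0 lymphocyte, 0 endothelial and 0 erythroid genes and 1 interferon gene passed as lower.

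Of 11 fetal and progenitor genes 4 fell (6 over the list alone; camera adjusted p = 0.00317, and adjusted p = 0.236 with an estimated correlation). H19, an imprinted RNA of fetal liver, went from 106 ± 78.0 to 0.160 ± 0.173 TPM (-7.10, SE 0.48, adjusted p = 6.72e-04), and Cdkn1c (-1.88), Igf2bp3 (-1.46) and Mest (-1.12) fell. Afp was at 2.01 ± 0.631 TPM in controls and 1.75 ± 1.37 TPM in Sox9 cKO (adjusted p = 0.662). Of 22 cell cycle genes 6 fell (18 over the list alone), with a median of -1.39 (camera adjusted p = 3.56e-05, and adjusted p = 0.456 with an estimated correlation). Top2a, a DNA topoisomerase, fell by 2.10 on the log2 scale, while Mki67 had a log2 fold change of -2.14 (adjusted p = 0.0693). Called fetal genes numbered 2, 1 and 1 without control replicates 1, 2 and 3. Called cell cycle genes numbered 1 without control replicate 2 or 3, 3 and 2 without Sox9 cKO replicates 1 and 2, and 13 without Sox9 cKO replicate 3. After median centring, and likewise after quantile normalization, 1 fetal and 1 cell cycle gene passed. With the sex-marker term 1 fetal gene and 0 cell cycle genes passed.

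Of 17 bile acid synthesis genes 2 rose, Cyp7b1 (log2 fold change 1.79, SE 0.45) and Scp2 (1.05, SE 0.19), and 3 over the list alone (camera adjusted p = 3.32e-05, and adjusted p = 0.215 with an estimated correlation, 0.132 after quantile normalization). Cyp7b1, an oxysterol hydroxylase, is also in the male-biased list, and its call was lost in 15 of 19 other settings. Without any 1 of the controls 0 bile acid synthesis genes passed. Cyp7a1, the rate-limiting enzyme of bile acid synthesis, was at 126 ± 50.2 and 61.3 ± 47.3 TPM (adjusted p = 0.245), and Cyp8b1 at 61.0 ± 26.3 and 85.0 ± 42.5 TPM (adjusted p = 0.513). Of 16 bile acid and bile lipid transport genes 2 rose, Slco1a1 and Abcg2 (0.89), and 3 fell, Abcb1a (-1.89), Slco1a4 (-1.86) and Abcc4 (-0.90, lost in 15 of 18 other settings), with 2 higher and 4 lower over the list alone and camera adjusted p = 0.129. Without control replicate 2 there were 1 higher and 0 lower transport genes. For that list the median was -0.19 while the mean (0.05) and the camera direction were upward. The bile salt export pump gene Abcb11 (0.11, adjusted p = 0.635), the bile acid importer gene Slc10a1 (0.55, adjusted p = 0.181) and Abcc3 (-0.20, adjusted p = 0.287) did not pass. Of 17 FXR and cholestasis response genes 2 fell, Sult2a1 and Cyp3a16, both also in the female-biased list (6 over the list alone, camera adjusted p = 0.345, 0.00412 after quantile normalization and 0.0218 without control replicate 3).

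Hepatocyte gene lists held few called genes, and without any 1 of the controls 0 identity, periportal, cholesterol synthesis or PPARA target genes passed. Of 25 secreted and identity genes Serpina1c rose (0.81, adjusted p = 0.0391) and 0 passed over the list alone. The list stood above other genes in the camera test (adjusted p = 0.00149, and adjusted p = 0.215 with an estimated correlation), with a median of 0.14 against -0.24 for all genes, and the direction turned after quantile normalization (adjusted p = 0.311). Alb was at 106683 ± 5086 TPM in controls and 78273 ± 3792 TPM in Sox9 cKO (log2 fold change -0.45, SE 0.29, adjusted p = 0.330). Its groups did not overlap, with 100900 to 110461 TPM in controls and 74907 to 82381 TPM in Sox9 cKO, so the missing call does not show an unchanged level. Of 19 periportal genes Cyp2f2 rose (1.04) and Hsd17b13 fell (-0.66), over all genes and over the list alone (camera adjusted p = 0.141, and 0.00839 without control replicate 3 and 0.00700 with array weights, above other genes). Of 20 pericentral genes 1 fell, Slc1a4 (-1.70), also over the list alone (camera adjusted p = 0.408, but 6.11e-04 with the sex-marker term, above other genes with a median of 0.21). Of 24 cholesterol synthesis genes 2 fell, among them Srebf2 (-0.92), and 4 over the list alone (camera adjusted p = 0.00745, and adjusted p = 0.624 with an estimated correlation). That call was lost without control replicate 3 (0.0775), without Sox9 cKO replicate 3 (0.154) and with array weights (0.567). Of 18 fatty acid synthesis genes 0 passed the limma test over all genes or over the list alone, although the list stood above other genes (camera adjusted p = 6.69e-04, and adjusted p = 0.456 with an estimated correlation, 0.351 after quantile normalization and 0.151 without Sox9 cKO replicate 2). With array weights 2 fatty acid synthesis genes rose, and likewise 2 with a replicate block. Of 22 PPARA target and fatty acid oxidation genes 1 fell, Pdk4 (-1.56), also over the list alone (camera adjusted p = 0.103, but 0.00452 with the sex-marker term, 0.0346 without control replicate 2 and 0.0119 without Sox9 cKO replicate 2, above other genes).

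**Figure D3:**
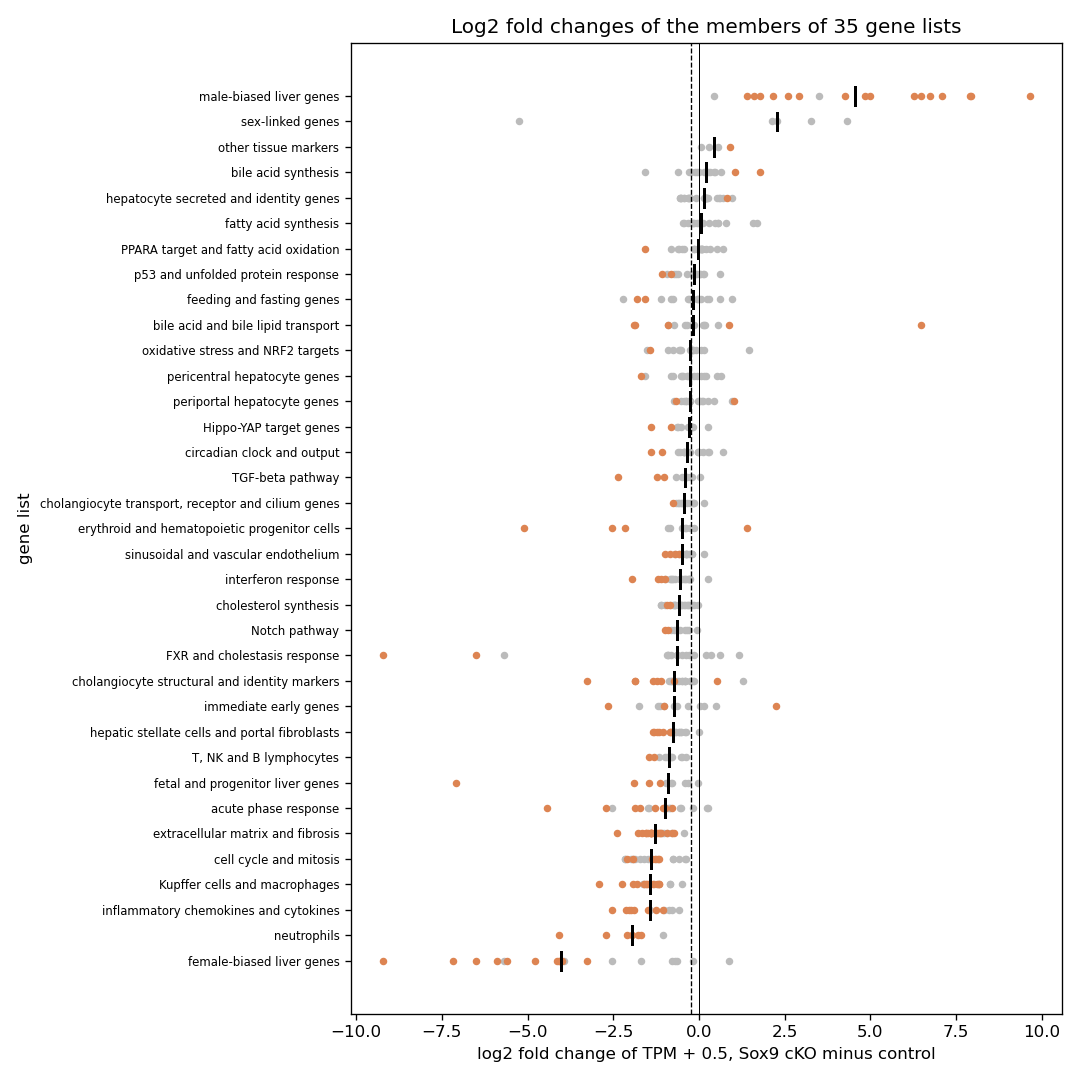
Each row is 1 of 35 gene lists, and points give the log2 fold change (TPM + 0.5, Sox9 cKO minus control) of its tested members, orange where adjusted p was under 0.05 and gray otherwise. Black ticks are list medians, from -4.03 for female-biased to 4.55 for male-biased genes, and the dashed line is the median of all tested genes, -0.24.

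In total the camera test placed 21 of 35 lists apart from other genes, 6 above and 15 below, while 0 were called with an estimated correlation (lowest adjusted p = 0.215, 6 at an unadjusted p under 0.05). Fry, which does not compare a list with other genes, called 18. These include the TGF-beta, FXR, erythroid and NRF2 lists, which camera with the preset correlation did not call. Some lists that camera called were not called by fry. They were hepatocyte identity (fry adjusted p = 0.844), fatty acid synthesis (0.781), sex-linked (0.198), bile acid synthesis (0.158) and cholesterol synthesis genes (0.0790). Cell cycle and interferon genes (both 0.0509) were not called by fry either.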

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

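The sex-marker term and the fit without control replicates 1 and 2 were chosen after the data were seen, and all other settings before. All 1202 calls kept their direction in every setting in which they were tested. Counts stayed within 1.5 times the reported 103 higher and 1099 lower genes with pseudocounts of 0.1 and 1, no filter, a minimum mean of 1 TPM, rescaling without the 50 most abundant genes and no variance trend. Lower genes numbered 430 with a minimum mean of 5 TPM, where fewer genes were tested, 284 after median centring and 215 after quantile normalization. Array weights gave 252 higher and 2312 lower genes. Leaving out 1 library gave 32 to 107 higher and 104 to 1003 lower genes, with fewer samples. The sex-marker term gave 21 and 49, and leaving out control replicates 1 and 2 gave 9 and 18, with 1 control left that is assumed to vary like the other group.

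The Sox9 level kept its direction but not its call after median centring (log2 fold change -0.91), quantile normalization (-0.66), the sex-marker term (-1.10) and without control replicates 1 and 2 (-1.10). Leaving out 1 library gave -1.35 to -0.97, with adjusted p from 0.0285 to 0.115. Over all settings its adjusted p ran from 0.00550 to 0.359. It was not tested with minimum means of 1 and 5 TPM.

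With a replicate block there were 85 higher and 563 lower genes, and Sox9 had a log2 fold change of -1.16 (adjusted p = 0.0643). Deviations of same-numbered samples correlated at -0.04, 0.00 and -0.03, so the numbers do not pair the samples, and 0 controls correlated best with their own number.

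Lists called higher numbered 2 after quantile normalization, and 0 lists were called higher and 0 lower with an estimated correlation. Hepatocyte secreted and identity genes turned direction after quantile normalization (adjusted p = 0.311). Sex-linked genes turned direction with the sex-marker term (0.806) and without control replicates 1 and 2 (0.781). Except where fewer genes or samples are named, the cause was not tested. Leaving out mitochondrially encoded genes was not run, because no such gene had a row. The depth of the libraries is unknown, so its effect on genes with low values could not be measured.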

Other observations

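All tests of explanations below were chosen after the results were seen, and the reading of the test on sex composition was changed after its value was seen, from excluding sex as the whole cause to leaving it open, because that evidence rests on 1 library.

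Lists of stress and rhythm genes were not set apart from other genes by camera, except the NRF2 list after quantile normalization (adjusted p = 0.0479), and the immediate early list had a median of -0.74. Among 13 immediate early genes Dusp1, a phosphatase induced by stress and glucocorticoids, rose (log2 fold change 2.25, SE 0.39, adjusted p = 0.0183), whereas Egr1 (-2.66) and Junb (-1.01) fell. Adjusted over the list alone there were 1 higher and 6 lower (camera adjusted p = 0.873). The Dusp1 call was lost in 4 of 19 other settings, with adjusted p up to 0.135, and the Egr1 call in 8 of 19. Lower immediate early genes numbered 0 without control replicate 2 or 3, without Sox9 cKO replicate 3 or after median centring. Hmox1, a heme-degrading enzyme, fell by 1.43 on the log2 scale, the 1 call among 15 NRF2 targets (1 higher and 2 lower over the list alone, camera adjusted p = 0.698). Per3 (-1.39) and Wee1 (-1.08) fell among 17 clock genes, with 0 called without control replicate 2 or 3 or after median centring and the Per3 call lost in 16 of 19 other settings (2 over the list alone, camera adjusted p = 0.959), Pmaip1 (-1.08) and Phlda3 (-0.82) among 18 p53 and unfolded protein genes (3 over the list alone, 0.622), with 0 called without any 1 control, without Sox9 cKO replicate 1 or after median centring, and Irs2 (-1.80) and Pdk4 (-1.56) among 16 feeding genes (3 over the list alone, 0.610), with 0 called without control replicate 1 and 1 without control replicate 2, without Sox9 cKO replicate 2 or 3, or after median centring. Of 4 tested markers of other tissues Fabp2, a fatty acid binding protein of intestine, rose from 88.7 ± 16.1 to 165 ± 13.3 TPM (0.90, 2 over the list alone, camera adjusted p = 2.58e-04, and adjusted p = 0.215 with an estimated correlation). The Fabp2 call was lost in 4 of 19 other settings, with limma adjusted p up to 0.330.

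Sprr1a was listed at 0 in every Sox9 cKO library and at 6.79 to 13.5 TPM in controls. Cml5 was listed at 0 in every control and at 6.46 to 12.8 TPM in Sox9 cKO, a gene singled out after its values were seen. Nnt, which carries a deletion in C57BL/6J mice, was at 48.5 ± 14.5 TPM in controls and 22.6 ± 2.72 TPM in Sox9 cKO (-1.04, SE 0.24, adjusted p = 0.0355), a call lost in 10 of 19 other settings, with adjusted p up to 0.182.

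The real grouping called 1202 genes, and the highest of the other splits called 1. Every other split mixes controls with Sox9 cKO libraries, so any group difference adds to its residual spread and lowers its count. Of the 10 splits of the 6 libraries 1, the real one, gave as many genes, and 10 splits are too few for a share under 0.05.

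Male-biased genes were higher and female-biased genes lower in Sox9 cKO, while 2 of 3 controls and 0 Sox9 cKO libraries expressed Xist. When libraries were split by sex marker, 0 male-biased and 2 female-biased members passed, against 16 and 11 by genotype, but this contrast rests on control replicate 3 alone, so sex composition and genotype cannot be told apart. An earlier postnatal stage of the controls also stays open, as ages are not in the labels. Among 11 fetal genes 7 were lower in every Sox9 cKO library than in every control, against 33.7% of other genes. The one-sided Fisher's exact test gave p = 0.0409, genes not being independent replicates. The fetal list had already been found lower in the same values. H19, Cdkn1c, Igf2bp3 and Mest were its 4 called members, while Afp did not pass (limma adjusted p = 0.662). Genotype could give the same count, so the test does not decide. Growth hormone, whose secretion pattern sets sex-biased liver expression, is a further candidate: Gh was listed at 0 in every Sox9 cKO library and at 2.01, 1.37 and 1.17 TPM in controls. Its induced genes Socs2 (log2 fold change -0.91, adjusted p = 0.610) and Igf1 (0.13, adjusted p = 0.512) did not pass in either direction, with Socs2 at 25.4, 1.48 and 58.6 TPM in Sox9 cKO. Of the other genes examined with them, Cish (-0.05, limma adjusted p = 0.979), Igfals (-0.26, 0.624), Ghr (0.09, 0.717) and Bcl6 (0.48, 0.666) did not pass. Cux2 (-4.15, adjusted p = 0.00246), which is in the female-biased list itself, and Stat5b (-0.71, adjusted p = 0.0370) fell. These values leave growth hormone open.

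The labels do not explain the Gh values or the sex-biased genes of control replicate 3. Whether these bear on the genotype of the controls, labelled wild type, was not tested and stays open. Sox9, at 1.43 to 1.69 TPM in controls and 0.19 to 0.68 TPM in the libraries labelled Sox9 cKO, differed in the direction the labels predict. That does not settle the labels, since 33.7% of tested genes outside the fetal list were also lower in every Sox9 cKO library. Whether controls carried Cre was not tested.

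Stromal and immune lists were lower in Sox9 cKO, with a median log2 fold change of -1.003 (quartiles -1.39 and -0.58) over 104 members of 6 lists. A shift of TPM composition as the whole cause is argued against only in that the members lay below the shift common to all genes. After median centring their median was -0.75 (quartiles -1.14 and -0.33). Centring moves all fold changes by the same amount, and camera had already placed these 6 lists below other genes. The centred values therefore restate that result and are not a separate test. Called members went from 53 to 24, and the cause of the lost calls was not tested. The macrophage median minus the endothelial median was -0.94 (permutation p = 6e-05, genes not being independent replicates). This argues against an equal loss of all cells other than hepatocytes only if each marker comes from a single cell type and expression per cell is unchanged. Neither condition was tested, so a common loss stays open. Sex, age and genotype stay open as explanations.

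Genes near Sox9 may differ through strain-derived sequence that came with the floxed allele. Within 10 Mb of Sox9, 29 of 225 tested genes were called (12.9%) against 9.48% elsewhere, an odds ratio of 1.41 (95% interval 0.918 to 2.11, two-sided Fisher's exact test, p = 0.0861), which does not decide it. Gh (chromosome 11, 106300271 to 106301865) lies in this interval and is 1 of the 29. In the same interval BC018473, singled out after its values were seen as Gh was, was listed at 0 in every Sox9 cKO library and at 4.43, 5.40 and 5.70 TPM in controls. No strain information beyond the labels was used here.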
